A study of Mus musculus with 12 samples.

How the data were processed

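Gene expression was measured by sequencing total RNA in 12 libraries of mouse primary cortical astrocytes, 3 in each of the groups labelled GFP, GADD45G, shLuc and shGADD45G. Groups were taken from the labels. The GFP columns were joined to them by name. Columns named G45g and shG45g were taken as GADD45G and shGADD45G, and columns named shCtrl as shLuc, the only control of that table, each with the same replicate number. The authors deposited 1 table per experiment. Per the file headers, each table holds read counts per gene, which were whole numbers in every library. The submitters' processing notes name STAR 2.5 for alignment to mm10, HTSeq 0.6.1 for counting and DESeq2, without parameters. The deposited signal columns are the counts divided by 1 size factor per library, as a comparison of the columns showed. The deposited FPKM values are counts scaled by the authors for gene length and library total. The deposited log2 fold changes are the authors' own, treated over control, and their sign was checked against the counts. The deposited p-value and adjusted p-value columns are likewise the authors' own. The library kit was stranded per the labels, and the strand setting of the counting is not given in the sources used here. The FPKM values were not used here, and the authors' fold changes and adjusted p-values were used only where named as the deposited table's.

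The overexpression table listed 25923 genes (17240 protein coding), and 24509 genes (16552 protein coding) were listed for the knockdown experiment, with 22845 in both. Of the gene identifiers, 99.9% and 100.0% were in the GENCODE M21 annotation, and 97.2% and 97.1% had the same coordinates there. Neither table held columns of other samples. Depth, the total count per library over listed genes, was 15626655 to 20756461. Replicates were compared by the chi-square per degree of freedom between pairs of libraries, over genes averaging at least 20 counts in the pair, where a value near 1 is counting error.

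Each experiment was fitted on its own 6 libraries with edgeR 4.0.16 in R 4.3.3, with its trimmed-mean (TMM) factors, its filterByExpr filter and its quasi-likelihood F test. No covariate was used. P-values were adjusted by Benjamini-Hochberg, and genes with an adjusted p under 0.05 were called. Levels in CPM, counts scaled to a common library total, used the TMM factors, and fold changes are on the log2 scale, treated minus control. Gadd45g was also given an exact two-sided permutation test of log2 CPM over the 20 assignments of 6 libraries, which cannot go below 0.1. A gene with 0 counts in a group was given a lower bound against a floor of 3 counts over the group. A gene with 1 to 3 counts was given a ratio with its 95% exact counting interval, and both cover counting error only.

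Lists of genes for 23 pathways and cell types were fixed before the data were examined. Each was tested with camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01, adjusted over the 23 lists. Calls with an estimated correlation and with fry are given beside it. Camera compares a list with the other genes, whereas fry asks whether the list's own genes move, on balance, one way. Members were also counted after adjustment over the list alone. Some genes stand in more than 1 list, such as H2-D1, H2-T23 and Psmb8 in the A1 and MHC class I lists. The named genes were Gadd45g, the 8 genes per direction with the largest fold change and up to 4 members per list with the smallest p. Those with the largest change were taken among called, protein-coding genes with a mean of at least 1 CPM, a named symbol and no overlap between the groups. Up to 5 genes called in the same direction and up to 5 in opposite directions in both experiments, with the smallest adjusted p, were also named. Some were left out for length. Erap1 and Fbln5 were named after their values were seen, as members that fell within lists called higher. The same holds for Sftpc and Hbb-bs, and in the closing section for Gfap in the overexpression experiment and the genes of the tissue lists.

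Overlap between the experiments was tested with Fisher's exact test, two-sided, for each of 4 pairs of directions among genes tested in both. The correlation of fold changes across genes was set against 81 regroupings of the libraries within the experiments. The experiments had separate controls, and genes are not independent replicates. Levels across all 4 groups came from a joint scaling of both tables over 15900 genes.

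The alternatives were relative log expression (RLE) factors, upper quartile factors, DESeq2 1.42.0, limma-voom, no filter on low counts, a stricter filter of at least 1 CPM in at least 3 libraries, and a minimum change of 2-fold. Further alternatives were the replicate number as a block, each library left out in turn, and all 12 libraries in one fit. The steps were tested on simulated data made by altering 200 genes. In the overexpression layout edgeR called 65.7%, 77.6% and 92.4% of genes changed 1.5-fold, 2-fold and 4-fold, with 16 false calls of 173. In the knockdown layout it called 46.3%, 85.1% and 93.9%, with 11 false calls of 161. In a separate simulation camera called 5 of 5 lists shifted 1.5-fold and 0 of 18 unchanged lists in each layout, with either correlation. Simulated genes varied independently of each other, so this gives no error rate for lists whose members vary together. With 200 genes altered, the simulation also does not test the scaling where most genes are called, as in the overexpression experiment (9300 of 15418).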

Results

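RNA sequencing was used to measure gene expression in primary astrocytes, the star-shaped glial cells of the brain, grown from the cortex of newborn wild-type mice. The cells had been transduced and then kept without serum for 1 week. The 12 libraries formed 4 groups of 3. In the overexpression experiment, libraries labelled GADD45G were set against libraries labelled GFP. In the knockdown experiment, libraries labelled shGADD45G were set against their controls, labelled shLuc. GADD45G belongs to a family of small stress-inducible proteins that bind the kinase MTK1, upstream of p38 and JNK. Total counts over all listed genes ran from 19480657 to 20756461 in the GFP libraries and from 17810863 to 18777231 in the GADD45G libraries. They ran from 16179509 to 18970492 in the shLuc libraries and from 15626655 to 18282315 in the shGADD45G libraries. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. That spread was uneven. The chi-square per degree of freedom between pairs of replicates was 2.11 to 3.15 in the GFP group, 2.23 to 2.98 in the shLuc group, 4.23 to 18.8 in the GADD45G group and 20.5 to 41.0 in the shGADD45G group.

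The targeted gene was examined first. Gadd45g (ENSMUSG00000021453) lies on chromosome 13 from 51846678 to 51848468 on the plus strand (mm10) and is annotated as protein coding. In the overexpression experiment its level was 121, 133 and 134 CPM (read counts scaled to a common library total) in the GFP libraries and 150, 144 and 139 CPM in the GADD45G libraries. The log2 fold change was 0.15 (SE 0.05, adjusted p = 0.0299 in edgeR's quasi-likelihood test). An exact two-sided permutation test of the log2 CPM gave p = 0.1, the smallest that 3 libraries against 3 allow. The edgeR call was lost without any single GFP library (0.0658, 0.0753 and 0.0671 without library 1, 2 and 3), without GADD45G library 1 (0.137), without a filter on low counts (0.0877) and with the replicate number as a block (0.0532). The species and extent of the introduced GADD45G sequence are not given in the sources used here, so its reads need not count toward the mouse gene. In the knockdown experiment Gadd45g stood at 140, 151 and 129 CPM in the shLuc libraries and at 67.2, 147 and 122 CPM in the shGADD45G libraries. The log2 fold change was -0.32 (SE 0.22, adjusted p = 0.408), the exact two-sided permutation p was 0.3, and without shGADD45G library 1 the log2 fold change was -0.05. The authors' deposited table gave log2 fold changes of 0.15 (adjusted p = 0.0380) and -0.32 (adjusted p = 0.651). All 3 GADD45G libraries lay above all GFP libraries, by a small margin. Of the shGADD45G libraries 2 of 3, libraries 1 and 3, lay below all shLuc libraries, and the difference between these groups did not pass the test. Groups are named below by their labels alone, and every direction is that between labelled groups. Of the other family members, Gadd45a was higher in GADD45G libraries (log2 fold change 3.24, SE 0.06) and in shGADD45G libraries (1.11, SE 0.14). Gadd45b was likewise higher in both, by 0.65 (SE 0.06) and 0.81 (SE 0.11). As a list, the family was called higher in GADD45G libraries (3 of 3 members, also adjusted over the list alone, adjusted p = 0.0277, and adjusted p = 0.385 with an estimated correlation). It was not called in shGADD45G libraries, where 2 of 3 members rose (adjusted p = 0.0542).

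**Figure D1:**
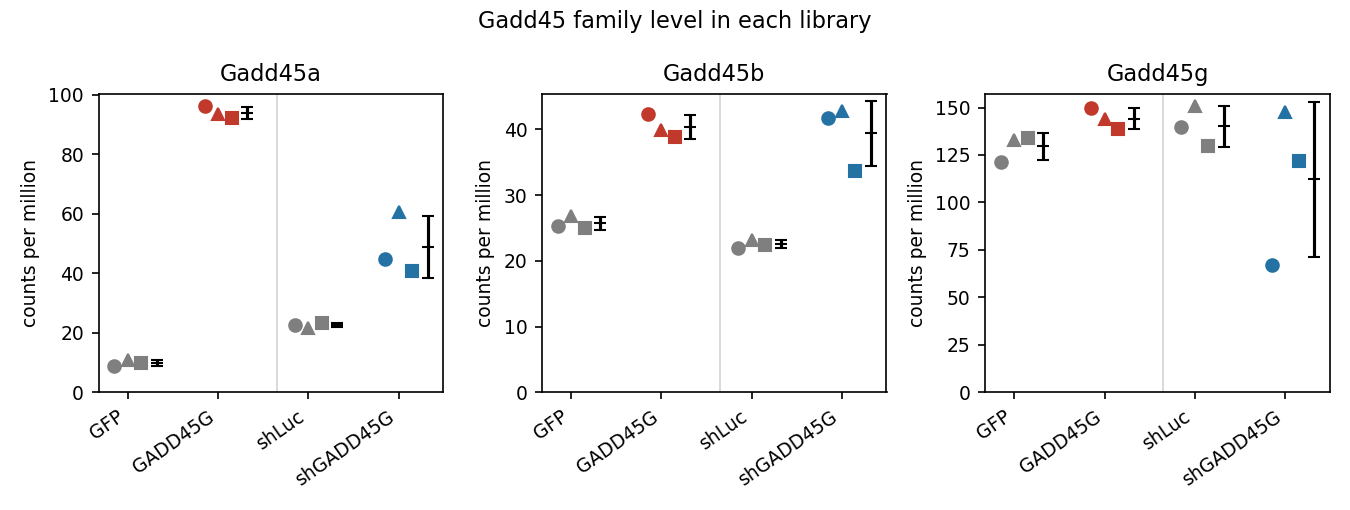
Level of Gadd45a, Gadd45b and Gadd45g in CPM in each of the 12 libraries (circle, triangle and square for replicates 1, 2 and 3), with the group mean and SD in black. Gadd45g ranges from 121 to 150 in the overexpression libraries, and shGADD45G library 1 lies at 67.2 while the other shGADD45G libraries lie at 147 and 122.

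The overexpression experiment asked which genes differ between GADD45G and GFP astrocytes. Most members of the type I interferon, NF-kB and MHC class I lists were higher in the GADD45G libraries. Ifi44, an interferon-induced gene, rose from 3.01 ± 0.510 to 280 ± 18.2 CPM (SD, n = 3 each), a log2 fold change of 6.54. Lcn2, which encodes the secreted siderophore-binding protein lipocalin 2, rose from 12.1 ± 0.940 to 432 ± 25.9 CPM, a log2 fold change of 5.16. All 8 tested neuron markers and 18 of 29 cell cycle genes were lower. Dcx, which encodes the microtubule-binding protein doublecortin of immature neurons, fell from 32.1 ± 1.22 to 0.275 ± 0.142 CPM. Of 15418 genes tested, edgeR called 9300 changed at an adjusted p under 0.05, of which 4716 were higher and 4584 lower in GADD45G libraries. At least 2-fold changes were called for 1398 higher and 1486 lower genes. The authors' deposited table held 4201 higher and 4183 lower genes at the same threshold. GADD45G library 3 stood apart from the other GADD45G libraries. It held 186 genes with at least 30 counts there and at most 5 over the other 5 overexpression libraries, 0.332% of its counts, among them the lung gene Sftpc and the hemoglobin gene Hbb-bs. Without it, 10143 genes were called. The GFP libraries stood apart from all other groups when the separate tables were scaled together. The mean of the shLuc libraries then lay nearer that of the GADD45G libraries than that of the GFP libraries for 7 of the 14 lists called below, the pan-reactive, NF-kB, p53, homeostatic, ependymal, cell cycle and neuron lists. For the others, among them the interferon, MHC class I, A1 and stress response lists, it lay nearer the GFP libraries. The interferon list had means of 3.47, 7.12, 4.73 and 5.34 log2 CPM in GFP, GADD45G, shLuc and shGADD45G libraries.

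The 8 named genes with the largest rises included further interferon-induced genes. Oas1a rose by 7.41 (SE 0.18) and its neighbour Oas1g by 6.48 (SE 0.44). Both lie on chromosome 5 and belong to one gene family, so reads could have been split between them. Oas1g rested on few GFP counts, and its log2 fold change was 7.65 without GFP library 3. Slfn8 rose by 6.43 (SE 0.13). Cdsn, which encodes the skin adhesion protein corneodesmosin, rose from 0.390 ± 0.241 to 38.9 ± 2.95 CPM, a log2 fold change of 6.60. Svep1 had 0 counts in the GFP libraries and 2.23 ± 1.98 CPM in the GADD45G libraries, at least 45.3-fold higher against a floor of 3 counts over the group, or at least 22.4-fold without GADD45G library 3. Mrgprf had 3 counts in the GFP libraries, a ratio of 98.0 with a 95% counting interval of 33.2 to 478. That ratio was 199.7 without GFP library 1 and 65.1 without GFP library 3. Slco2a1, with a ratio of 199 (67.8 to 970), stood at 9.85 ± 15.5 CPM in the GADD45G libraries. Its ratio was 17.9 without GADD45G library 3, 393 without GFP library 2 and 132 without GFP library 3. These intervals and floors cover counting error only, and a bound against 0 counts shrinks when a library is left out of the group at 0. Egfem1 fell from 136 ± 1.94 to 0.367 ± 0.110 CPM (log2 fold change -8.50). Genes without a count in the GADD45G libraries were the serotonin receptor gene Htr5a, at least 116-fold lower, the embryonic muscle myosin gene Myh3, at least 109-fold lower, and the homeobox gene Gsx1, at least 54.1-fold lower. The same held for the myelin gene Mobp, at least 51.4-fold lower, for Zfp985, at least 50.8-fold lower, and for Snx31, at least 38.9-fold lower. The synaptic vesicle gene Sv2c had 3 counts in the GADD45G libraries against 1095, a ratio of 325 (111 to 1580), or 652 without GADD45G library 3.

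All 28 tested members of the type I interferon list rose, with a median log2 fold change of 3.48 (camera, adjusted p = 7.4e-21, and adjusted p = 0.0725 with an estimated correlation). They included the transcription factor gene Irf7 (4.76), the antiviral genes Ifit1 (5.08) and Rsad2 (5.40), and Oas1a. Of the MHC class I antigen presentation list, 13 of 14 rose and Erap1, which encodes a peptide-trimming protease, fell by 0.14 (median 1.78, adjusted p = 4.3e-09, and adjusted p = 0.0535 with an estimated correlation). H2-K1 rose from 292 ± 2.83 to 1377 ± 25.5 CPM and H2-T23 from 6.38 ± 0.905 to 218 ± 7.70 CPM. The H2 genes are closely related, and their single values are uncertain where reads were shared. All 12 tested pan-reactive astrocyte genes rose (median 1.90, adjusted p = 2.4e-09, and adjusted p = 0.0535 with an estimated correlation). Among them were Lcn2, the chemokine gene Cxcl10 (4.92), the ceruloplasmin gene Cp (3.56) and the oncostatin M receptor gene Osmr (2.35). Of the A1 reactive list, which shares 3 members with the MHC class I list, 7 of 11 rose, 1 fell (2 without GADD45G library 3) and 3 did not pass (adjusted p = 0.00153, and adjusted p = 0.0725 with an estimated correlation). The interferon-inducible GTPase genes Iigp1 (4.84) and Gbp2 (2.89) rose, and Fbln5 fell by 1.06. Of the A2 reactive list, 7 of 11 rose and 3 fell, and the list was not called (adjusted p = 0.238). Its member Ptx3 rose by 2.57 and Cd109 fell by 1.33.

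Of the NF-kB cytokines and regulators, 18 of 22 rose and 3 fell (median 1.35, adjusted p = 2.0e-05, and adjusted p = 0.0535 with an estimated correlation). The chemokine gene Ccl2 rose by 4.75 and the adhesion gene Vcam1 by 1.98, whereas the chemokine gene Cxcl5 fell by 3.44 and Traf1 by 1.59. Complement genes were split, with 5 of 10 higher, 1 lower and 4 not passing (adjusted p = 0.0707), or 5 higher and 3 lower without GADD45G library 3. C3, the central complement component, rose from 80.2 ± 4.20 to 2115 ± 75.4 CPM, and C4b rose by 3.24. With the separate tables scaled together, C3 also stood high in shLuc (1657 CPM) and shGADD45G libraries (1402 CPM), so for this gene the GFP libraries were those apart. Serping1, a C1 inhibitor gene, rose by 1.99, or by 1.35 without GADD45G library 3. Of the p53 targets 18 of 24 rose and 3 fell, with a median of 0.35 (adjusted p = 0.000352, and adjusted p = 0.385 with an estimated correlation). Gdf15, a stress-induced secreted factor, rose by 3.28 and Plk2 by 1.09. In the unfolded protein and integrated stress response list 11 of 19 rose and 5 fell (adjusted p = 0.00968, and adjusted p = 0.250 with an estimated correlation). The largest rises were those of Trib3 (6.26) and of the cystine transporter gene Slc7a11 (6.13), and the asparagine synthetase gene Asns rose by 1.95.

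Cell cycle genes were lower, with 18 of 29 falling, 2 rising (1 without GFP library 1 or 3) and 9 not passing (median -0.70, adjusted p = 0.00968, and adjusted p = 0.385 with an estimated correlation). The cyclin gene Ccna2 fell from 9.58 ± 0.624 to 2.34 ± 0.473 CPM and Top2a by 0.68, while the kinesin gene Kif11 rose by 0.56. Of the synaptogenic and phagocytic factors, 8 of 13 fell, 1 rose (3 without GADD45G library 3) and 4 did not pass (adjusted p = 0.0335, and adjusted p = 0.250 with an estimated correlation). The glypican gene Gpc5 fell by 4.53 and the phagocytic receptor gene Megf10 by 1.14, and the thrombospondin gene Thbs1 rose by 0.94. Of the cholesterol synthesis genes 11 of 20 fell and 2 rose (adjusted p = 0.0431, and adjusted p = 0.385 with an estimated correlation). That call was lost without GADD45G library 3 (0.0755), without GADD45G library 2 (0.0550) and without GFP library 1 (0.0504). Dhcr7, the last enzyme of the pathway, fell by 0.97. Of the homeostatic astrocyte genes 12 of 19 rose and 5 fell (adjusted p = 0.0304, and adjusted p = 0.581 with an estimated correlation). The lipid carrier gene Apoe rose by 1.21, and the glycolytic gene Aldoc fell by 2.21.

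The following 3 lists were not called. Of the extracellular matrix and scar genes 12 of 21 rose and 6 fell (adjusted p = 0.126). The matrix glycoprotein gene Tnc rose from 34.5 ± 0.777 to 984 ± 53.4 CPM, and the laminin gene Lama1 fell by 4.53. Of the neurotrophic factors 8 of 14 rose and 5 fell (adjusted p = 0.643), with a median of 0.73 and a mean of -0.17. Ptn, which encodes the growth factor pleiotrophin, fell from 1273 ± 2.99 to 18.3 ± 1.89 CPM. With the separate tables scaled together, it was also low in shLuc (48.7 CPM) and shGADD45G libraries (38.7 CPM). Of the MAPK and AP-1 list 10 of 24 rose and 8 fell (adjusted p = 0.643, median -0.11 and -0.29 to 0.04 in leave-one-out fits, mean 0.29), or 10 and 11 without GADD45G library 3, with the stress-response factor gene Atf3 higher by 4.38 and Etv5 lower by 1.04.

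Markers of other cell types moved as well. All 8 tested neuron markers fell (median -3.62, adjusted p = 0.000293, and adjusted p = 0.0725 with an estimated correlation). In leave-one-out fits the filter on low counts was run anew and let in further members. There 9 or 10 were tested, 7 to 9 fell and the median was -1.94 to -1.62. Over the 8 members tested with all libraries, 8 fell without GADD45G library 3, with a median of -3.95. Scaled together, the separate tables gave a mean of the neuron list of 2.95 log2 CPM in GFP libraries, against 0.37 in GADD45G, 0.28 in shLuc and 0.19 in shGADD45G libraries. The markers included Stmn2, from 174 ± 3.42 to 63.5 ± 3.82 CPM, and Tubb3 (-1.51). Gad2, a GABA-synthesizing enzyme gene, had 1 count in the GADD45G libraries, in library 3, a ratio of 161 (28.6 to 6407). Without that library it had 0 counts and was at least 35.9-fold lower, and without GADD45G library 2 the ratio was 107. All 7 ependymal markers rose (median 1.20, adjusted p = 0.00126, and adjusted p = 0.0725 with an estimated correlation), among them Foxj1, the regulator of motile cilia, from 261 ± 3.13 to 816 ± 42.6 CPM. Of the oligodendrocyte lineage list 3 of 7 rose and 2 fell (adjusted p = 0.970, median 0.45, mean -1.95). Without GADD45G library 3 there were 3 higher and 3 lower with a median of 0.20. Among its members Olig1 rose by 0.59, and Mobp, without a count in the GADD45G libraries, was at least 51.4-fold lower. Of the fibroblast and mural list 4 of 7 rose and 3 fell, the smooth muscle gene Acta2 by 1.36. Without any single GFP library 1 rose. Without GADD45G library 3 it had 2 higher and 3 lower, and its median went from 0.91 to -0.51. The endothelial markers Vwf (3.60) and Flt1 (2.66) were higher and Kdr fell from 138 ± 3.80 to 13.0 ± 3.17 CPM. Without GADD45G library 3 Vwf stood at 1.41, and Flt1 at 0.92 with adjusted p = 0.104. The Flt1 call was also lost without any single GFP library, and the endothelial median was 0.92 without GADD45G library 3. Neither list was called (adjusted p = 0.643 for each), and with all libraries camera's direction was down for both while the medians were 0.91 and 2.66. Microglia and macrophage markers depended on GADD45G library 3. With all libraries 0 of 17 rose and 2 fell in edgeR (3 at an unadjusted p under 0.05, 2 called by DESeq2, list adjusted p = 0.254). Without any other single library 1 fell, and 1 rose without GADD45G library 1 or 2. Without library 3, 14 of 17 fell, with a median of -1.41 (adjusted p = 0.00029). Ctss changed sign, from 2.36 (adjusted p = 0.0738) to -1.19 without it. Adjusted over the list alone, counts were the same for all lists but 4. The p53 list then had 19 higher, the cell cycle list 19 lower, the extracellular matrix list 13 higher and the microglia list 1 lower. None of the 14 lists called by camera's preset correlation, 10 higher and 4 lower, was called with an estimated correlation. The estimate was below the preset 0.01 for the A1 (-0.035), NF-kB (-0.019), neuron (-0.058), ependymal (-0.005) and MHC class I (0.009) lists. A higher correlation cannot account for the loss of those calls. For the other called lists the estimate was 0.03 to 0.73. In camera the MHC class I list went from adjusted p = 4.3e-09 to 0.0535 at nearly the same correlation. The loss of the other calls therefore cannot be put down to correlation alone.

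**Figure D2:**
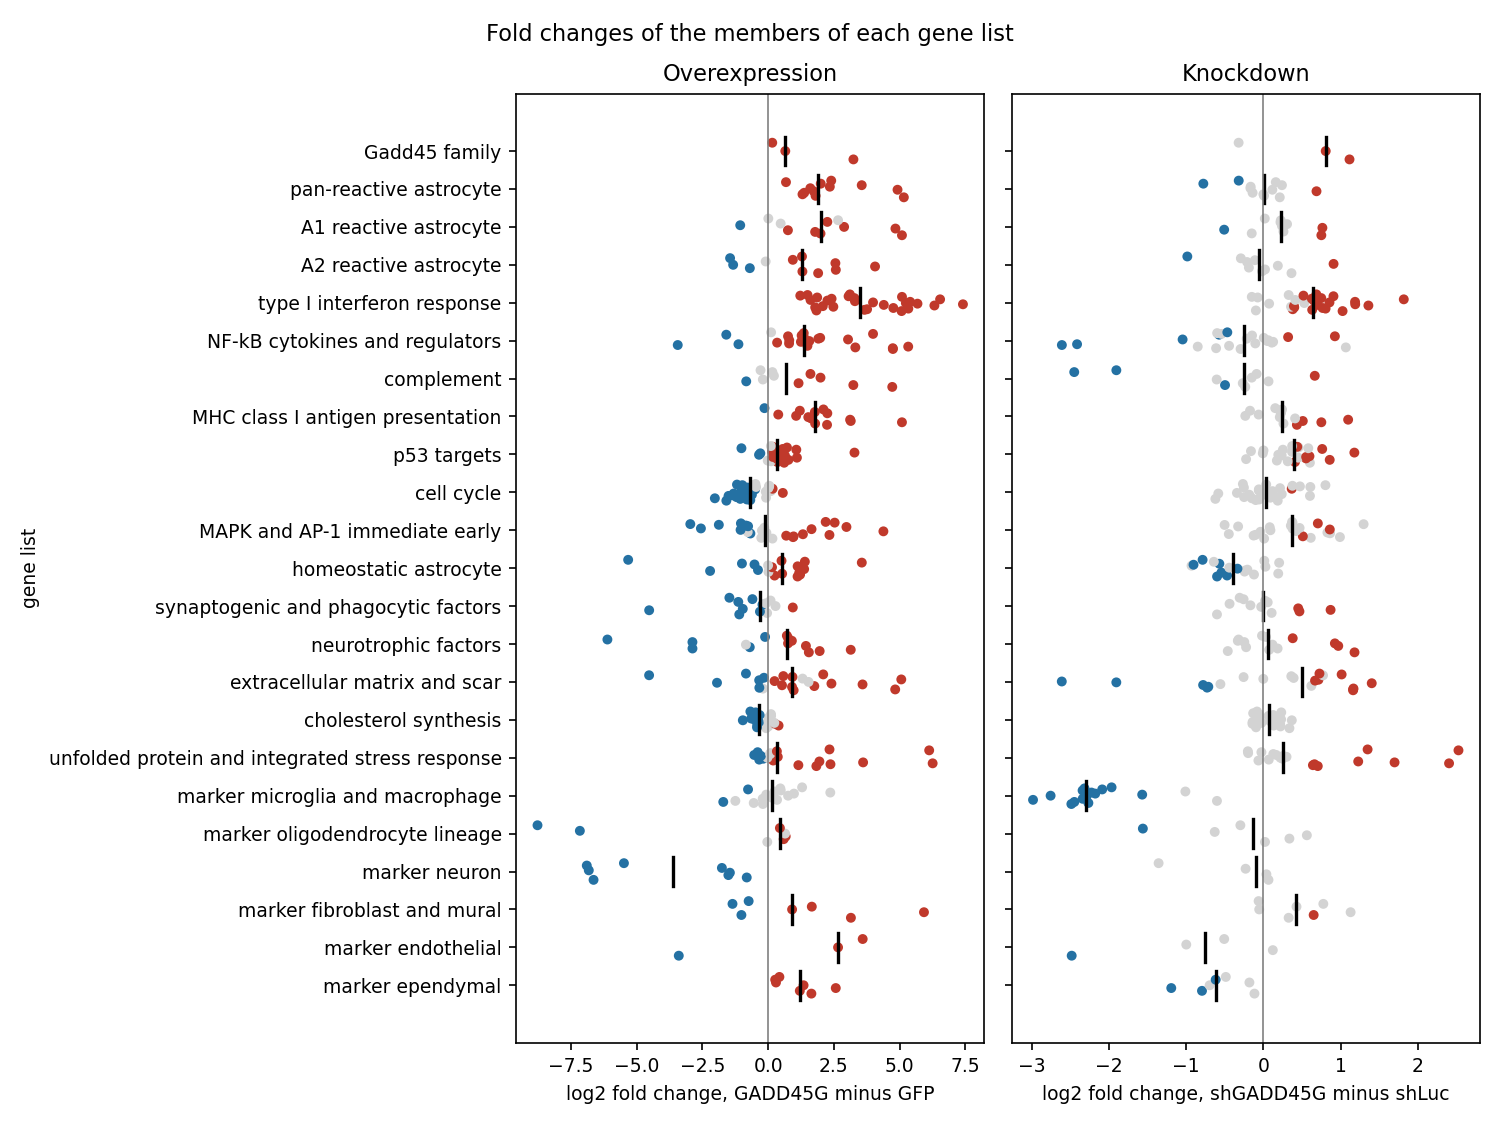
Log2 fold change of each tested member of the 23 gene lists in the overexpression experiment (left, GADD45G minus GFP) and the knockdown experiment (right, shGADD45G minus shLuc, on a narrower scale). Red points rose and blue points fell at an adjusted p under 0.05, gray points did not pass, and black bars are list medians, such as 3.48 and 0.64 for the type I interferon list and 0.15 and -2.29 for the microglia and macrophage list.

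The knockdown experiment asked which genes differ between shGADD45G and shLuc astrocytes. Of the markers of microglia and macrophages, the immune cells of brain and tissue, 15 of 17 were lower in the shGADD45G libraries, a list call also lost with an estimated correlation (adjusted p = 0.349). Spi1, which encodes the myeloid transcription factor PU.1, fell from 11.6 ± 1.25 to 1.34 ± 0.327 CPM (SD, n = 3 each), a log2 fold change of -3.12. Of the type I interferon list 20 of 28 members were higher (8 to 23 in leave-one-out fits), among them Rsad2, from 14.7 ± 1.98 to 33.5 ± 3.16 CPM. Of the unfolded protein and integrated stress response list 8 of 19 were higher, among them Trib3, from 6.47 ± 0.674 to 34.3 ± 10.8 CPM. These lists' calls were lost with an estimated correlation (adjusted p = 0.349 for each). Of 14914 genes tested, edgeR called 1554, with 768 higher and 786 lower in shGADD45G libraries. Changes of at least 2-fold were called for 106 higher and 332 lower genes. The authors' deposited table held 909 higher and 938 lower genes. The count depended on single libraries: it was 2745 without shGADD45G library 1, and 539, 538 and 613 without shLuc library 1, 2 or 3. The mitochondrial share of counts was 1.67%, 2.20% and 3.35% in shGADD45G libraries 1, 2 and 3, against 2.10%, 2.09% and 2.20% in the shLuc libraries.

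Besides Spi1, 7 named genes had the largest falls. Spn, the gene of the leukocyte surface protein CD43, fell by 3.62 (SE 0.41) and Marco, a macrophage scavenger receptor gene, by 3.50 (SE 0.34). The integrin gene Itgal fell from 24.2 ± 4.03 to 2.55 ± 0.979 CPM. Emilin2 fell by 3.58, Lrmp by 3.44, and Clec4a2 and Adap2 by 3.08 each. These values moved with single shGADD45G libraries. Spn stood at -4.32 and Adap2 at -4.63 without library 3, and Lrmp at -4.28 without library 2. The Adap2 call was lost without shLuc library 2 (adjusted p = 0.0518). Among the named genes Cdsn had the largest rise, from 0.114 ± 0.0991 to 5.17 ± 3.03 CPM, with a log2 fold change of 5.41 (6.33 without shLuc library 3). Pappa, a metalloproteinase gene, rose by 2.63, Slc7a11 by 2.53, Trib3 by 2.40 and the stress-response gene Nupr1 by 2.13.

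Of the microglia and macrophage markers 15 of 17 fell and 2 did not pass, with 16 lower adjusted over the list alone (median -2.29, adjusted p = 4.7e-18, and adjusted p = 0.349 with an estimated correlation). Aif1 fell from 8.49 ± 1.03 to 1.52 ± 0.536 CPM and the complement gene C1qc from 38.3 ± 3.07 to 7.83 ± 3.11 CPM. Tyrobp fell by 2.18 and Laptm5 by 2.09. The marker list's median log2 CPM was 4.31, 4.51 and 4.15 in the shLuc libraries and 1.04, 2.26 and 2.68 in the shGADD45G libraries. Complement genes were called lower, with 3 of 10 falling and 1 rising (1 to 4 and 0 to 1 in leave-one-out fits), also adjusted over the list alone (adjusted p = 0.0231, and adjusted p = 0.393 with an estimated correlation). The receptor gene C5ar1 fell by 2.45, and the receptor gene C3ar1 by 1.91, a value of -2.67 without shGADD45G library 3. The C3ar1 call was lost without any single shLuc library or shGADD45G library 2. The list's call was lost without shGADD45G library 1 (0.200). Of the NF-kB list 5 of 22 fell and 2 rose (6 and 3 adjusted over the list alone, and 3 and 0 without any single shLuc library), without a call (adjusted p = 0.0542). The cytokine gene Tnf fell by 2.61 and Tnfaip2 by 1.05. The falls of receptor and cytokine genes stood beside that of the microglia markers in the same libraries.

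**Figure D3:**
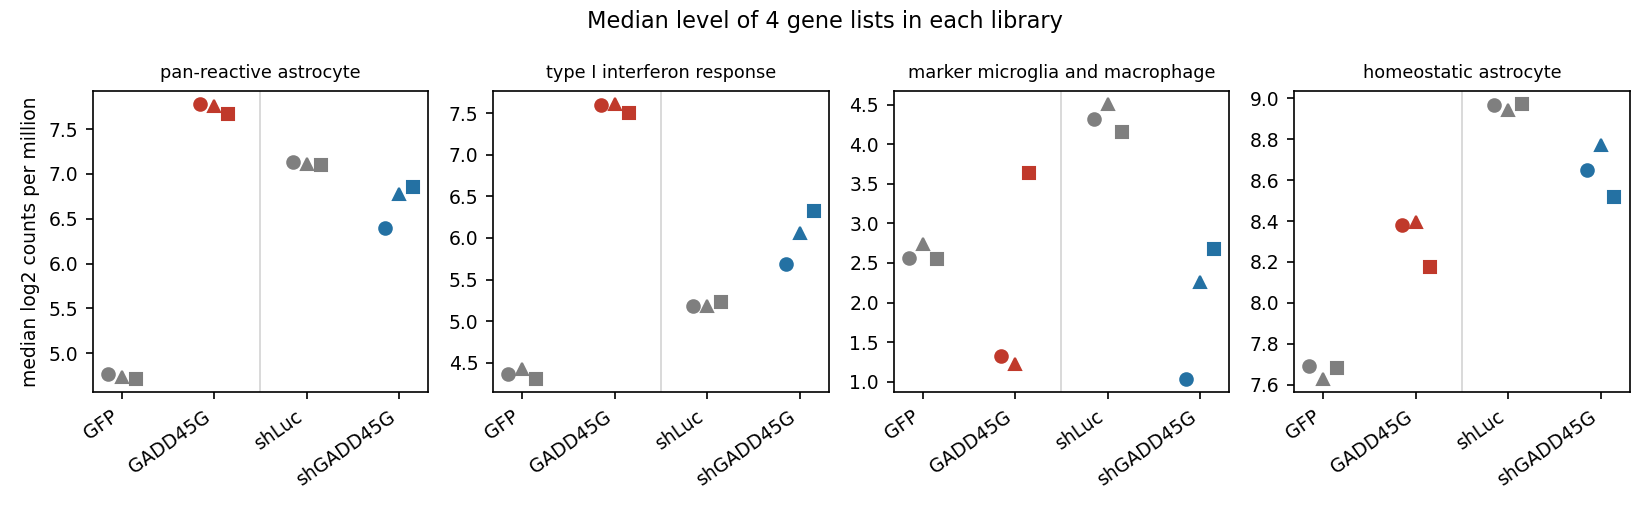
Median log2 CPM over the members of 4 gene lists in each of the 12 libraries (circle, triangle and square for replicates 1, 2 and 3), each experiment scaled separately, with a gray line between the experiments. For microglia and macrophage markers GADD45G library 3 lies at 3.64 while the other GADD45G libraries lie at 1.33 and 1.22, and all 3 shGADD45G libraries lie below the lowest shLuc library at 4.15.

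Of the type I interferon list 20 of 28 rose and 8 did not pass (8 rose without shLuc library 1 or 2), with 23 higher adjusted over the list alone (median 0.64, adjusted p = 2.7e-12, and adjusted p = 0.349 with an estimated correlation). Ifi44 rose from 17.0 ± 1.22 to 60.1 ± 24.4 CPM, Rsad2 by 1.19, Ifit1 by 1.03 and Irf7 by 0.77. Of the MHC class I list 4 of 14 rose (1 to 6 in leave-one-out fits), or 5 adjusted over the list alone (adjusted p = 0.00305, and adjusted p = 0.413 with an estimated correlation), a call lost without shGADD45G library 2 (0.0598). H2-Q7 rose by 1.10, and H2-K1 by 0.43, the latter without a call when any single shLuc library was left out. Of the p53 targets 8 of 24 rose (3 to 11 in leave-one-out fits), or 12 adjusted over the list alone (median 0.39, adjusted p = 7.6e-06, and adjusted p = 0.359 with an estimated correlation). The death receptor gene Tnfrsf10b rose by 0.76, and Zmat3 and Sesn2 by 0.55 each. Of the unfolded protein and integrated stress response list 8 of 19 rose, or 10 with 1 lower adjusted over the list alone (adjusted p = 6.7e-06, and adjusted p = 0.349 with an estimated correlation). Besides Slc7a11 and Trib3, the lipoprotein receptor gene Vldlr rose by 1.35 and Asns by 1.23, from 31.5 ± 1.39 to 73.9 ± 10.9 CPM.

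Homeostatic astrocyte genes were lower in shGADD45G libraries, with 7 of 18 falling and 11 not passing (4 lower without any single shLuc library and 11 without shGADD45G library 1), or 9 lower adjusted over the list alone (median -0.39, adjusted p = 2.1e-05, and adjusted p = 0.177 with an estimated correlation). Ndrg2 fell from 318 ± 4.99 to 170 ± 34.3 CPM, the fatty acid enzyme gene Acsl6 by 0.79, Mlc1 by 0.57 and the gap junction gene Gja1 by 0.55. Of the ependymal markers 3 of 7 fell (0 without shLuc library 1 and 6 without shGADD45G library 1), or 4 adjusted over the list alone (median -0.62, or -0.39 without shGADD45G library 3, adjusted p = 0.00191, and adjusted p = 0.349 with an estimated correlation). Ak7 fell by 0.62, a call lost without shLuc library 1 (adjusted p = 0.0511). None of the 8 lists called by camera's preset correlation, 4 higher and 4 lower, was called with an estimated correlation. The estimate was -0.04 for the homeostatic list, below the preset 0.01, so a higher correlation cannot account for that loss. For the other called lists it was 0.13 to 0.73, and their loss cannot be put down to correlation alone either.

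The remaining lists were not called. Of the pan-reactive genes 1 of 12 rose and 2 fell, also adjusted over the list alone (adjusted p = 0.582). Without shGADD45G library 1 there were 5 higher and 2 lower, with camera's direction turned from down to up, and without any single shLuc library 0 fell. Gfap, the intermediate filament gene of astrocytes, fell from 1029 ± 6.57 to 824 ± 78.6 CPM (adjusted p = 0.0439), a call lost without any single shLuc library. Of the A1 list 2 of 10 rose and 1 fell, or 4 and 1 adjusted over the list alone (adjusted p = 0.0994, 1 to 5 higher in leave-one-out fits), with Iigp1 at 0.76 and Ggta1 at -0.51. Of the A2 list 1 of 10 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.643, 0 to 2 higher and 0 to 3 lower in leave-one-out fits). Of the extracellular matrix and scar list 8 of 20 rose and 5 fell, or 10 and 6 adjusted over the list alone (adjusted p = 0.0691, 2 to 6 lower in leave-one-out fits). The fibronectin gene Fn1 rose from 71.0 ± 4.44 to 159 ± 24.6 CPM, Lamc1 by 0.73 and Cyr61 by 0.71, and Tgfb1 fell by 1.91. Of the neurotrophic factors 4 of 14 rose, also adjusted over the list alone (adjusted p = 0.179, 2 higher without any single shLuc library), with Bdnf at 1.18 and Vegfa at 0.97. Of the synaptogenic and phagocytic factors 3 of 12 rose, or 3 with 3 lower adjusted over the list alone (adjusted p = 0.643, 1 to 3 higher in leave-one-out fits), with Gpc6 at 0.87. Of the MAPK and AP-1 list 3 of 23 rose, also adjusted over the list alone (adjusted p = 0.0590, 0 higher without any single shLuc library). In the cell cycle list 1 of 29 passed in edgeR, Mcm7 at 0.37 (adjusted p = 0.0484), and 0 adjusted over the list alone, against 5 at an unadjusted p under 0.05 and 2 in DESeq2. The Mcm7 call was lost without any single library but shGADD45G library 3. In the cholesterol synthesis list edgeR called 0 of 20, also adjusted over the list alone, against 2 at an unadjusted p under 0.05 and 1 in DESeq2. Of the oligodendrocyte lineage list 1 of 6 fell, or 2 adjusted over the list alone (adjusted p = 0.328) and 2 without shGADD45G library 2. Of the neuron list edgeR called 0 of 4, against 1 at an unadjusted p under 0.05, 0 in DESeq2 and 1 lower adjusted over the list alone. Without shGADD45G library 2 it called 1, Gad1 (-1.96, adjusted p = 0.0315). Of the fibroblast and mural list 1 of 7 rose, Col1a2 by 0.65, or 2 adjusted over the list alone (adjusted p = 0.0799) and 2 without shGADD45G library 1 or 3. Of the endothelial list 1 of 4 fell, also adjusted over the list alone (adjusted p = 0.165, 0 to 2 lower in leave-one-out fits).

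The design also allows the experiments to be set side by side, since they share no control libraries. Of 14624 genes tested in both, 1084 were called in both, 644 in the same direction between labelled groups and 440 in opposite directions. Genes higher in both GADD45G and shGADD45G libraries numbered 411, against 240 for independent calls (Fisher's exact test, odds ratio 2.68, adjusted p = 1.4e-38 over 4 pairs of directions). Genes lower in both numbered 233, against 209 (adjusted p = 0.0957). Opposite pairs numbered 230 against 225 (higher in GADD45G, lower in shGADD45G, adjusted p = 0.680) and 210 against 224 (adjusted p = 0.361). Without shGADD45G library 1, an alternative chosen after the data were seen, 1081 genes moved the same way and 878 in opposite ways. The Pearson correlation of fold changes across genes was 0.0538 and Spearman's rho 0.0442, and 41 of 81 regroupings of libraries within the experiments gave an r as large. Pearson's r was 0.125 without GADD45G library 3, an alternative chosen after the data were seen, and 0.0294 with DESeq2. The highest r of the regroupings, made with all libraries, was 0.148 in size. Genes are not independent replicates. Every regrouping left the labels unevenly mixed and so kept part of the difference between labelled groups. The regroupings therefore cannot tell whether the correlation differs from none.

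Members called in both experiments were higher in both for 20 of 20 interferon genes, 8 of 8 p53 targets, 8 of 8 unfolded protein and integrated stress response genes and 4 of 4 MHC class I genes. Homeostatic astrocyte genes went the other way in 5 of 6 cases and ependymal markers in 3 of 3, higher in GADD45G and lower in shGADD45G libraries. Single genes with the smallest adjusted p in both included Mthfd2, a mitochondrial folate enzyme gene, higher by 2.78 and 1.48 in the overexpression and knockdown experiments. The amino acid transporter gene Slc7a1 (2.34 and 1.25), Glce (1.02 and 1.59) and Vldlr (2.33 and 1.35) were also higher in both, and Fcrls, a microglial gene, was lower in both (-1.29 and -2.46). Genes of opposite direction included the endothelin receptor gene Ednrb (0.57 and -1.09), Ttyh1 (0.80 and -0.86) and Rida (0.93 and -0.89). The matrix gene Ltbp2 (-0.47 and 0.95) and the guidance gene Slit2 (-0.46 and 1.02) were lower in GADD45G and higher in shGADD45G libraries.

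**Figure D4:**
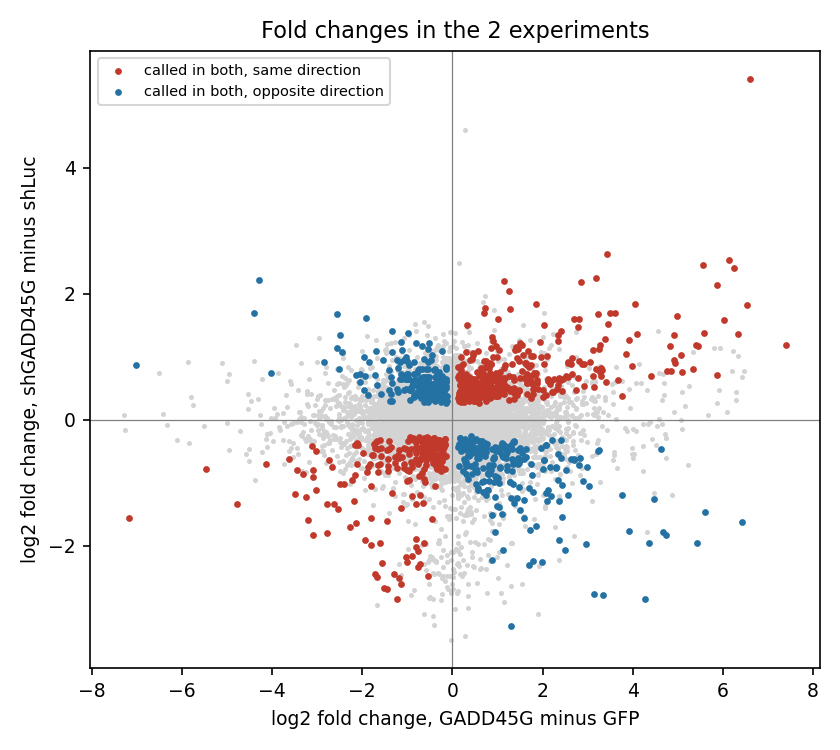
Log2 fold change of each gene tested in both experiments, GADD45G minus GFP on the horizontal axis and shGADD45G minus shLuc on the vertical axis. Red points are the 644 genes called in both in the same direction, blue points the 440 called in opposite directions, and gray points all others.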

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

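Of the alternatives below, leaving out GADD45G library 3 or single shGADD45G libraries for the overlap and the correlation between experiments was chosen after the data were seen, and all others were chosen before the data were examined. In the overexpression experiment 8165 to 10143 genes were called over all alternatives except the minimum of 2-fold, which left 2884. In no alternative was a gene called in the reported fit called in the opposite direction, in either experiment. For the knockdown, all 12 libraries in one fit called 2670 genes and a minimum of 2-fold left 438. Leave-one-out counts ran from 538 to 2745: they were 539, 538 and 613 without shLuc library 1, 2 or 3, and 2745, 1464 and 1744 without shGADD45G library 1, 2 or 3. With the replicate number as a block, 8948 and 1570 genes were called. Correlations across genes of deviations from the group mean, between libraries of the same number, ran from -0.009 to 0.012 in the overexpression experiment and from -0.024 to 0.080 in the knockdown experiment, so the numbers gave no sign of pairing. Gadd45g in the overexpression experiment lost its call with no filter (0.15, adjusted p = 0.0877 in edgeR), with the block (0.16, 0.0532) and in the fit of all 12 libraries (0.14, 0.551), and ran from 0.10 to 0.18 in leave-one-out fits. With an estimated correlation 0 lists were called in either experiment. In the overexpression experiment adjusted p was then 0.0535 for the pan-reactive, NF-kB and MHC class I lists, 0.0725 for the A1, interferon, neuron and ependymal lists and 0.250 for the synaptogenic and stress response lists. It was 0.385 for the Gadd45 family, p53, cell cycle and cholesterol lists and 0.581 for the homeostatic list. For the knockdown lists it was 0.349 for the interferon, stress response, microglia and ependymal lists, 0.393 for complement, 0.413 for MHC class I, 0.359 for p53 and 0.177 for the homeostatic list. With the block, complement (0.0304) and extracellular matrix (0.0315) were called in the overexpression experiment and MAPK (0.0471) in the knockdown experiment. Fry called 22 lists in the overexpression experiment, adding A2 (0.000409), complement (0.000509), MAPK (0.00475), extracellular matrix (0.000601), oligodendrocyte (1.7e-05), fibroblast (0.0132) and endothelial (0.0054) lists, and it called the neurotrophic list in the opposite direction, lower (0.000235). For the knockdown, fry added the Gadd45 family (0.0301), A1 (0.0410), NF-kB (0.0460), synaptogenic (0.0489), neurotrophic (0.0117), extracellular matrix and oligodendrocyte (0.00715 each) and fibroblast (0.0135) lists. It lost complement (0.0747), MHC class I (0.0978), p53 and ependymal (0.0513 each). Leave-one-out ranges of adjusted p in the overexpression experiment were 0.0220 to 0.0755 for cholesterol, 0.0295 to 0.153 for complement and 0.00029 to 0.803 for microglia. Between shGADD45G and shLuc libraries 7 to 13 lists were called, with 0.0357 to 0.105 for the Gadd45 family, 0.0127 to 0.192 for NF-kB, 0.0192 to 0.498 for MAPK, 0.0383 to 0.0794 for extracellular matrix, 0.0301 to 0.0937 for fibroblast, 0.00501 to 0.200 for complement and 2.9e-05 to 0.0598 for MHC class I. Ctss in the overexpression experiment ran from -1.19, without GADD45G library 3, to 2.95. Opposite changes in both experiments numbered 407 to 878 in leave-one-out fits, highest without shGADD45G library 1. Pearson's r between experiments ran from 0.0294 to 0.125 over all its alternatives. Over all alternatives, named genes kept direction and side of the threshold in 1526 of the values in the overexpression experiment, with 5 newly called, 13 no longer called and 1 reversed, which was Ctss. In the knockdown experiment 1412 were kept, with 39 newly called, 99 no longer called and 0 reversed. For all of these the cause was not tested. Alternatives fixed for tables without counts, a pseudocount and a filter on mean values, were not run, since the tables hold counts. Depth limits genes with few counts: those with 0 counts in a group have only a lower bound.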

Other observations

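The families of gene symbols, the comparison of all 4 groups by where the shLuc mean lies, the fibroblast and shGADD45G library 2 tests and all tests on GADD45G library 3 were chosen after the result was seen. Of 86 families of symbols with at least 15 tested genes, 3 were called in the overexpression experiment by camera's preset correlation. Cfap genes, which encode proteins of cilia and flagella, rose in 27 of 30 cases and fell in 2 (median 1.00, adjusted p = 1.1e-05 in limma's camera, and adjusted p = 0.903 with an estimated correlation). Trim genes, many of them ubiquitin ligases of antiviral defence, rose in 28 of 44 cases and fell in 6 (median 0.52, adjusted p = 0.000849, and adjusted p = 0.903 with an estimated correlation). Zinc finger genes named Zfp fell in 139 of 361 cases and rose in 45 (median -0.16, adjusted p = 0.0343, and adjusted p = 0.903 with an estimated correlation). In the knockdown experiment genes named Cd, for surface antigens of leukocytes, fell in 15 of 49 cases and rose in 1 (adjusted p = 1.8e-05, and adjusted p = 0.298 with an estimated correlation). Of 9 families called there, Cfap fell in 2 of 30 cases (adjusted p = 0.0119, and adjusted p = 0.723 with an estimated correlation), the opposite direction to the overexpression experiment. Trim rose in 5 of 42 cases and fell in 1 (adjusted p = 0.0306, and adjusted p = 0.617 with an estimated correlation). The others, besides Cd, Pcdhb and Rpl, were Rps and Usp (adjusted p = 0.617 with an estimated correlation for each) and Nup and Zbtb (adjusted p = 0.582 with an estimated correlation for each), all with direction up. The clustered protocadherins named Pcdhb fell in 2 of 19 cases (adjusted p = 0.000941, and adjusted p = 0.582 with an estimated correlation). Ribosomal protein genes named Rpl rose in 4 of 65 cases (adjusted p = 0.00452, and adjusted p = 0.708 with an estimated correlation).

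Each experiment has 10 splits of its 6 libraries into 3 and 3, too few for a share under 0.05. Every split but the real one mixed the labels, which puts the difference between labelled groups into the spread within groups. Low gene counts in those splits therefore do not test the calls. In the overexpression experiment 1 of the 10 splits, the real one, gave 9300 genes, and the highest other gave 0 in edgeR (153 at an unadjusted p under 0.05, against 9888). For lists the real split gave 14 and the highest other 9. For the knockdown 1 of 10 splits, again the real one, gave 1554 genes, and the highest other gave 0 in edgeR (476 at an unadjusted p under 0.05, against 3790). For lists the real split gave 8 and the highest other 7.

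The GFP libraries stood apart from the other 3 groups when both tables, which are separate, were scaled together: 126 of 15900 genes lay over 3 log2 units from the mean of the other groups, which lay within 1 of each other, against 10 for GADD45G, 3 for shLuc and 0 for shGADD45G. Of the 126 genes, 120 were higher and 6 lower in GFP libraries. Egfem1 had 136 CPM in GFP libraries and 0.363, 0.557 and 0.464 in GADD45G, shLuc and shGADD45G libraries. Gfap, which did not reach that distance, had 226, 1180, 1038 and 829. A difference between the 2 tables as a whole is argued against as the whole cause, since 1 gene separated the tables. Cultures or transduction of the GFP group may have differed in something other than GADD45G: the shLuc mean lay nearer GADD45G for 66.8% of genes changed at least 2-fold, past a bound of 50% set after some of these genes, but not the share, had been seen. A comparison added after that value was seen gave 72.1% for GFP lying nearer shGADD45G among knockdown genes, so the measure is not specific and this stays open, as does GADD45G expression as the only source of the rise, with shLuc nearer GADD45G in 5 of the 10 lists called higher, and it lay nearer for the neuron list too.

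Microglia and macrophage markers were lower in all 3 shGADD45G libraries. Fewer microglia or macrophages in those cultures is a candidate explanation: a second list of such genes, written before its values were looked at, had a median of -2.37, with 18 of 19 lower. Scaled together, the separate tables gave a mean of the first list of 4.11 log2 CPM in shLuc libraries. It was 1.89 in shGADD45G, 2.38 in GFP and 1.84 in GADD45G libraries, so the shLuc group stood apart. The second list holds markers of the same cells, read in the same libraries, so its fall is no separate test. It cannot tell fewer such cells in the shGADD45G cultures from more in the shLuc cultures, or from lower levels of these genes within the cells. An equal fall of all cells other than astrocytes is argued against as the whole cause, for the lists tested. The microglia list had a median of -2.29 (-1.90 without shGADD45G library 1), and no other cell type list had a median as low. The fibroblast and mural list, chosen after the result was seen, had a median of 0.43 (0.32 to 0.67 in leave-one-out fits). Its members ran from -0.06 to 1.13, above the microglia list's range of -2.99 to -0.60, although 1 of its 7 members passed. Its median log2 CPM in shGADD45G library 3 was 0.64, below every shLuc library. Some members had few counts, such as Col3a1, at 0.281 CPM in shLuc and 0.639 CPM in shGADD45G libraries. The oligodendrocyte and neuron lists, neither called, had medians of -0.14 and -0.10. The fibroblast list alone could not decide this, and a smaller fall of these cells stays open. Ependymal markers (adjusted p = 0.00191 in limma's camera, and adjusted p = 0.349 with an estimated correlation) and endothelial markers (not called) had medians of -0.62 (-0.85 to -0.39) and -0.75 (-1.32 to -0.53), so a lower share of some other cells besides microglia stays open. Knockdown of Gadd45g stays open as a cause: shGADD45G library 2, with Gadd45g at 147 CPM, had a marker median 1.89 below the lowest shLuc library (a difference of -1.89), and 1 library cannot exclude it.

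GADD45G library 3 held transcripts of other tissues. RNA from lung, liver and blood is a candidate source: 13 of 14 lung genes had at least 10 times the level of every other overexpression library (29625 counts, 0.166% of the library), as did 9 of 11 liver genes and 8 of 11 blood genes, against 0 of 8 kidney genes and 2 of 12 muscle and heart genes. Scgb1a1 had 14868 counts against at most 3 elsewhere, Sftpc 7520 against at most 1, Hbb-bs 4653 against 0 and Alb 2171 against at most 1. Hemoglobin genes are close paralogs, so their single counts are uncertain. A swap with a GFP library is argued against, since 0 GFP libraries lay nearer the GADD45G group, and the library's own mean correlation was 0.978 with GADD45G and 0.912 with GFP libraries.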
